A study of Arabidopsis thaliana with 72 samples.

How the data were processed

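The samples were 72 RNA sequencing libraries of hypocotyls and cotyledons of 5-day-old Arabidopsis thaliana seedlings (ecotype Columbia, WT and the mutants pif7-1 and sav3-2). Per the labels, RNA was extracted with RNeasy Micro columns and libraries were made with the TruSeq RNA kit. The deposited files hold FPKM, mapped fragments scaled to transcript length and to the total of the library, which the authors made with Cufflinks, 1 table per library. CASAVA 1.8.2, TopHat2 2.0.8b, Cufflinks 2.1.1 and the genome build TAIR10 are named with the samples, while read length, read type and annotation version are not given in the sources used here. FPKM is scaled within a library, and read counts were not used here.

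Of 33557 gene identifiers in the files, 32810 were matched to the TAIR10 annotation used here, and 32809 of these overlapped the annotated interval. Depth was estimated from the steps between low FPKM values of genes of known transcript length: 80.0% of the low values of 2968 genes lay within 0.1 of a whole step. This gave 14590000 to 28140000 fragments for hypocotyl libraries and 16620000 to 26530000 for cotyledon libraries. The steps were used for depth alone, and no count-based interval was computed.

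Each library was divided by the median of its ratios to the geometric mean over 14889 genes with an FPKM of 1 or more in every library (factors 0.757 to 1.36). Values given as FPKM in the results are scaled in this way, with standard deviations (SD) between libraries. Genes with an FPKM of 1 or more in at least 2 libraries were tested, and 38 of these with a failed estimate in any library were left out, leaving 21076. Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit, eBayes with trend), with 1 mean for each of the 34 groups and 38 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and a fold threshold of 2 was used for 1 description.

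The comparisons were low against high R:FR per tissue and time in WT, F tests over the 6 times, the interaction of tissue and light, the overlap between tissues, the tissues at 0 h, the high R:FR time course against 0 h, low against high R:FR in each mutant, the difference between mutant and WT responses (genotype by light), and mutant against WT in each light. Chance overlap was computed from the counts per direction. Genes called in WT at both 2 and 4 h in 1 direction were followed in the 3 h libraries, with limma's fry for the set. In all, 23 gene lists were tested with limma's camera (inter-gene correlation of 0.01) on 20 contrasts, 460 tests adjusted together, of which 173 were called and 76 of those held with an estimated correlation. Counts of list members cover the genes that passed the filter; of 17 root markers 3 did. Tests of lists at 0 h and between genotypes in high R:FR stand outside this family.

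These comparisons, the lists, the named-gene rule and the other settings were fixed before the data were examined. The rule took, for each tissue's response, the 10 highest and 10 lowest mean changes over the 6 times among genes past the F test and called at 2 or more times with no overlap between the libraries. It took the 6 highest and 6 lowest for the tissue difference and for 0 h, the 8 highest and 8 lowest response differences and the 5 highest and 5 lowest high R:FR differences per mutant and tissue, the 4 highest and 4 lowest changes at 7 h in high R:FR, PIF7, TAA1, and members of the lists as examples. Which members serve as examples, and the values of ST2A, LHY and other rule-named genes in comparisons where the rule did not pick them, were chosen after their values were seen.

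Libraries were matched to the WT high R:FR time course by the 22 clock genes, and for the time-matched comparisons WT was interpolated between its time points. WT high R:FR libraries between 0 and 7 h were matched with their own time left out of the course, all other libraries with every time kept. To measure sequence shared between genes, 50-base stretches of each gene were searched in the genome, and 1162 of 20815 genes had 5% or more shared. The time matching, the shared sequence, the exclusion of 7 libraries and the 1 h control for 0.5 h were chosen after seeing the data. The other settings chosen beforehand were a pseudocount of 0.1, no filter, a stricter filter (mean FPKM of 5), FPKM as deposited, quantile normalization, a replicate block, a fit within the tissue, genes with failed estimates kept, and leaving out each library in turn. The latter leaves groups of 1 library, assumed to vary like the others. The pipeline was tested on simulated data with 100 genes changed by each size among 21076 and no other differences between groups. For the pif7-1 response difference in the hypocotyl it recovered 25 of 100 genes changed by 0.5 on the log2 scale. Of those changed by 1 it recovered 70.0%, with 6 false calls. Simulated samples of 5 and 6 h were matched at 5 and 6 h. They were interpolated between the same WT means that served for matching, so this result was built in. Matched with their own time left out, WT high R:FR libraries of 1 h fell at 1.4 to 1.6 h and those of 3 h at 2.7 to 3.1 h.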

Results

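The series holds 72 RNA sequencing libraries from 5-day-old Arabidopsis thaliana seedlings of the ecotype Columbia, split into the hypocotyl (the seedling stem) and the cotyledons (the seed leaves). Shade from neighbouring plants was imitated by light with a low ratio of red to far-red (low R:FR), and mock-treated seedlings stayed in light with a high ratio (high R:FR). Wild-type (WT) seedlings were sampled in high R:FR at 0 h and in both lights at 0.5, 1, 2, 3, 4 and 7 h, with n = 2 libraries per tissue, light and time. At 3 h the mutants pif7-1 (n = 2) and sav3-2 (n = 3) were sampled in both tissues and lights. PIF7 is a transcription factor of the phytochrome pathway, and SAV3 is another name of TAA1, the aminotransferase that starts auxin synthesis from tryptophan. This gives 34 groups. The values used here are FPKM, and read counts were not used. From the steps between the lowest values, the depth was estimated at 14590000 to 28140000 fragments per library (median 19570000), with 16950 to 19050 genes at an FPKM of 1 or more. Replicates correlated across genes with Pearson's r of 0.974 to 0.994 on the log2 scale. What the replicates were (separate plants, dishes or days) is not given in the sources used here, so the p-values measure the spread between these samples. Changes are on the scale of log2(scaled FPKM + 1), which shrinks changes of weakly expressed genes. Adjusted p of single genes come from limma, over 21076 genes unless said to be adjusted over a list alone. Those of gene lists come from limma's camera and are adjusted over the list tests. Errors of log2 changes are limma standard errors (SE). In simulated data the fit recovered 31 of 100 genes changed by 0.5 and 89 of 100 changed by 1 on the log2 scale in a comparison of 2 against 2 libraries, with 5 false calls. No other genes were changed there. The real comparisons called far more genes, so their number of false calls cannot be read from the simulation.

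Before treatment, photosynthesis genes were lower in the hypocotyl than in the cotyledon, and markers of the shoot tip and of dividing cells were higher there. At 0 h 11176 genes differed, 6623 higher and 4553 lower in the hypocotyl. Of the list of light-harvesting and Calvin cycle genes, 24 of 25 were lower, among them LHCB1.1 at -2.48 (SE 0.24) and RBCS2B at -2.66 (SE 0.33), and so were 13 of 14 chlorophyll and carotenoid genes (14 when adjusted over the list alone). All 13 shoot apex markers were higher in the hypocotyl, led by the homeobox gene KNAT1 at 4.88 (SE 0.18) (79.6 ± 19.6 against 1.71 ± 0.256 FPKM, mean ± SD, n = 2). The same held for 13 of 15 cell division genes and all 3 tested root markers (of 17 in the list, the others not passing the filter), with PIN2 at 2.24 (SE 0.26) and CASP1 at 2.80 (SE 0.51). Of 10 guard cell markers 5 were lower, KAT1 by the most at -2.87 (SE 0.18). The largest differences of protein-coding genes were NRT1.5, a nitrate transporter, at 6.15 and the glycine-rich protein gene GRP9 at 6.02, and, lower in the hypocotyl, AT1G23130 at -7.74, AT3G16660 at -7.66 and AT3G16670 at -6.50. The share of higher genes among those called was 59.3%. It was 87.0% on FPKM as deposited, which moved the median of all genes by 0.46 on the log2 scale, and 48.5% after quantile normalization.

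In high R:FR alone, many genes changed over the 7 h of sampling, which is the background to every comparison below. LHY, a morning transcription factor of the circadian clock, fell from 647 ± 100.1 FPKM at 0 h to 4.45 ± 1.46 at 7 h in the hypocotyl, a log2 change of -6.91 (SE 0.24), and by -7.05 (SE 0.24) in the cotyledon. PRR7, which represses LHY later in the day, rose by 5.55 (SE 0.14) and 5.86 (SE 0.14). At 7 h 10 of 22 clock genes were higher and 10 lower in the hypocotyl, and 12 higher and 8 lower in the cotyledon. Past the test over all times were 15363 genes in the hypocotyl and 15650 in the cotyledon. The largest changes at 7 h included rises of AT5G62360 (5.99, hypocotyl), AT1G74929 (6.42, cotyledon) and AT1G56300 (6.17, cotyledon), and falls of RVE2, a MYB-like clock-related gene (-5.78, hypocotyl), and AT1G26790 (-5.71, cotyledon). For AT1G74929 the call over all times was lost without replicate 2 of the 7 h cotyledon.

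In the WT hypocotyl, the genes with the strongest rises in low R:FR included PIL1, RTFL18, SAUR22, IAA19 and ATHB2. PIL1 (AT2G46970, chromosome 2, 19295490 to 19297826) encodes a transcription factor that is switched on early in shade. It rose from 1.43 ± 0.414 to 121 ± 3.46 FPKM at 1 h, a log2 change of 5.66 (SE 0.15) (limma adjusted p = 1.56e-28), and stood 3.92 higher at 7 h. RTFL18 (AT5G16023, chromosome 5, 5232731 to 5232886) codes for a small peptide of the DEVIL/ROTUNDIFOLIA family and had the largest mean change over the 6 times, 5.63. Its annotated interval is short, and how well FPKM holds at such a length was not tested. SAUR22, whose family is induced by auxin and promotes cell expansion, rose by 4.62 at 0.5 h, 6.92 at 1 h and 2.90 at 7 h. IAA19 (AT3G15540, chromosome 3, 5264024 to 5265678), an auxin-induced repressor of auxin signalling, went from 0.88 at 0.5 h to a highest value of 5.72 (SE 0.23) at 2 h. ATHB2, a homeodomain transcription factor and classic shade marker, was highest at 0.5 h, at 5.70 (SE 0.19).

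Low against high R:FR in the hypocotyl called 5452 genes at 0.5 h (2845 higher, 2607 lower), 3021 at 1 h (1860, 1161), 6114 at 2 h (2889, 3225), 6432 at 3 h (2843, 3589), 7419 at 4 h (3040, 4379) and 8825 at 7 h (3854, 4971). At 3 h 970 of them changed by a factor of 2 or more. Over all times 13595 genes passed the F test, and 139 were higher and 37 lower at all 6 times. The 10 strongest mean rises of the naming rule were RTFL18, PIL1, SAUR22, IAA19, ATHB2, SAUR23, SAUR21, SAUR19, SAUR28 and SAUR24, from 3.62 to 5.63. Each was called at 2 or more times with both low R:FR libraries above both high R:FR libraries. The strongest mean falls included ICL, the isocitrate lyase of the glyoxylate cycle (-2.68), DIN2, a sugar-starvation and dark-induced glucosidase (-2.51), the late embryogenesis genes LEA18 (-2.79) and AtLEA4-1 (-2.35), the xyloglucan endotransglucosylase XTH31 (-2.28), and AT1G65970 (-2.56), AT3G02480 (-2.32) and AT5G64100 (-2.13). At 0.5 h the result rested on the control: against high R:FR at 1 h, a comparison chosen after seeing the data, low R:FR at 0.5 h called 521 genes, 274 of them also called in the same direction against the 0.5 h control. Without single libraries the counts moved by over 1.5 times as follows: at 0.5 h to 2670 without high R:FR replicate 1, at 1 h to 1387 without high R:FR replicate 2 and 1876 without low R:FR replicate 1, at 2 h to 4035 without low R:FR replicate 1, and at 4 h to 4728 without high R:FR replicate 1. The share of higher genes was 52.2% at 0.5 h, 61.6% at 1 h and 47.2% at 2 h, and on FPKM as deposited 29.5%, 43.3% and 35.5%; after quantile normalization it was 48.1%, 49.2% and 48.3%. Fitted within the tissue, the 1 h count was 1982.

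**Figure D1:**
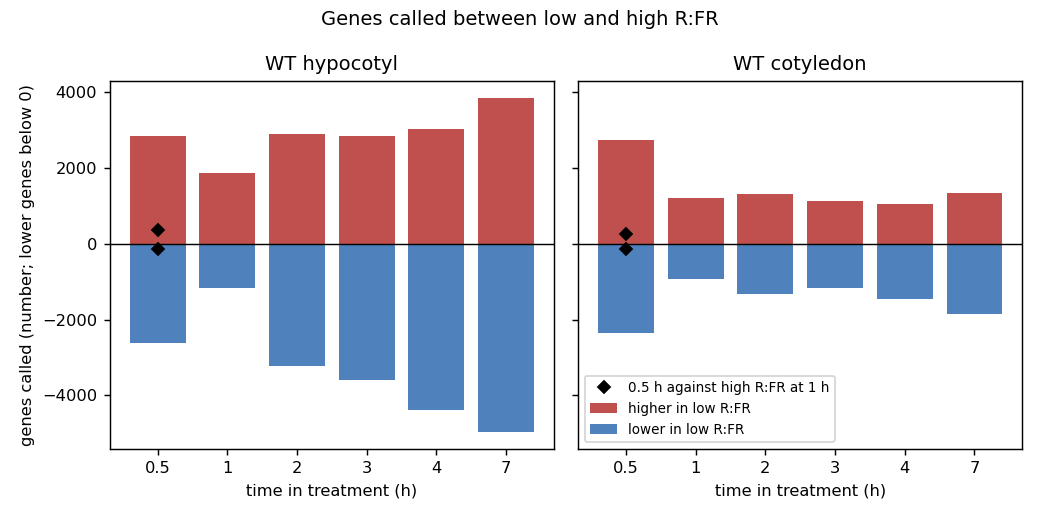
Genes called between low and high R:FR in WT at each time in the hypocotyl (left) and the cotyledon (right), as numbers of genes; bars above 0 are genes higher in low R:FR and bars below 0 are lower genes, and diamonds mark the same counts at 0.5 h against the high R:FR libraries of 1 h. The hypocotyl counts run from 3021 at 1 h to 8825 at 7 h in total, and the cotyledon stays at or below 3198 after 0.5 h.

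Grouped by the lists fixed beforehand, most SAUR, auxin-induced and shade marker genes rose in the hypocotyl from 1 h onward. Of 28 SAUR genes, 22 rose at 0.5 h, 27 at 1 h, 26 at 2 h, 27 at 3 h, 27 at 4 h and 25 at 7 h, and none fell (from 0.5 to 7 h, 23, 27, 26, 27, 27 and 25 rose when adjusted over the list alone, which at 7 h also gave 1 fall). Of 18 auxin-induced IAA, GH3 and ACS genes 8 rose at 0.5 h and 16 at 2, 3 and 4 h, with IAA6 at 5.05 (SE 0.25) and the auxin-conjugating enzyme gene GH3.5 at 2.96 (SE 0.16) at 2 h. Of 18 shade marker genes 8 rose at 0.5 h, 15 at 1 h and all 18 at 2 h (8, 17 and 18 adjusted over the list alone). Against high R:FR at 1 h, 21 SAUR genes, 6 auxin-induced genes and 9 markers rose at 0.5 h. Expansins and xyloglucan endotransglucosylases, which loosen and remodel the cell wall, followed later. Of 17, 3 rose at 0.5 h, 7 at 1 h and 15 at 3 and 4 h (15 adjusted over the list alone), such as EXPA8 at 3.19 (SE 0.22) and XTH17 at 2.98 (SE 0.31). Ethylene genes rose from 2 h, 9 of 12 at 3 h (10 adjusted over the list alone), with the ACC synthase ACS11 at 3.87 (SE 0.20) and the receptor ETR2 at 1.51 (SE 0.17). Of 11 auxin transport genes 6 rose at 2 h, including PIN3 at 1.76 (SE 0.12) and PIN7 at 2.06 (SE 0.13). Of 16 brassinosteroid genes 11 rose at 3 h, with BR6OX1 at 2.3 (SE 0.15), and of 14 gibberellin genes 5 rose and 3 fell, with the biosynthesis gene GA20OX1 at 3.93 (SE 0.20) at 1 h. Of 13 cytokinin genes 7 fell and 2 rose at 3 h, among the falls the type-A response regulators ARR6 (-1.61 (SE 0.23) at 4 h) and ARR4 (-1.31 (SE 0.17)). At 0.5 h 8 of them were lower, but none of these were called against high R:FR at 1 h. In limma camera tests, all 6 times were called for the SAUR genes, the markers and the auxin-induced genes, and the wall list was called from 1 h. With an estimated correlation these held except for the auxin-induced genes at 0.5 h (adjusted p = 0.160) and the wall list at 1 h (adjusted p = 0.192). The ethylene call held from 2 to 4 h and was lost at 7 h (adjusted p = 0.0520), and the transport list at 2 h had an adjusted p of 0.0689 with an estimated correlation.

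Late in the hypocotyl time course, pigment genes fell. At 7 h 13 of 14 chlorophyll and carotenoid genes were lower, among them HEMA1, which commits glutamate to tetrapyrrole synthesis (-0.70 (SE 0.13)), the camera call being lost with an estimated correlation (adjusted p = 0.188). Of 18 flavonoid genes 12 fell at 4 h and 10 at 7 h (14 and 10 adjusted over the list alone), with CHS, the first enzyme of the pathway, at -1.56 (SE 0.37) and LDOX, an anthocyanin enzyme, at -2.59 (SE 0.43). Those camera calls were lost as well (adjusted p = 0.446 at 4 h and 0.606 at 7 h with an estimated correlation). At 0.5 h 7 of the list were higher, but against high R:FR at 1 h 1 was lower and the others were not called. Shoot apex markers, which are high in the hypocotyl samples, fell for 6 of 13 at 3 h, with CUC2 at -0.96 (SE 0.26), and 1 of 3 root markers rose and 2 fell at 7 h (PIN2 1.54, CASP1 -1.93).

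In the WT cotyledon shade markers rose too, and 3 auxin synthesis genes of the YUCCA family rose with them. YUC9 (AT1G04180, chromosome 1, 1104623 to 1105988), a flavin monooxygenase gene of the last step of auxin synthesis, went from 0 ± 0 to 29.1 ± 0.437 FPKM at 0.5 h, a log2 change of 4.91 (SE 0.17) (limma adjusted p = 7.46e-25), and stood 2.67 higher at 7 h. YUC8 rose from 2.62 ± 0.212 to 36.0 ± 4.12 FPKM at 3 h and YUC2 from 4.04 ± 0.109 to 15.6 ± 0.919. In the hypocotyl at 3 h, low R:FR levels of the 3 genes were 0.163, 1.28 and 0.678 FPKM. TAA1 itself moved the other way in the cotyledon, by -1.30 (SE 0.26) at 4 h.

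Low against high R:FR in the cotyledon called 5102 genes at 0.5 h (2745 higher, 2357 lower), 2120 at 1 h (1202, 918), 2620 at 2 h (1306, 1314), 2307 at 3 h (1134, 1173), 2510 at 4 h (1054, 1456) and 3198 at 7 h (1340, 1858). Over all times 9359 genes passed the F test, and 87 were higher and 9 lower at all 6 times. Named by the rule were PIL1 (mean change 4.69), ST2A, a sulfotransferase acting on hydroxyjasmonate (4.41), IAA29 (4.21), RTFL13 (4.01), ATHB2 (3.98), HFR1, a repressor of shade growth (3.93), SAUR22 (3.86), AT3G21330 (3.67), YUC9 (3.51) and FLP1 (3.25). The strongest mean falls were smaller: the lectin gene JAL33 (-1.63), the type-A response regulators ARR6 (-1.43) and ARR7 (-1.07), the glutathione transferase gene GSTU8 (-1.09), MEE3 (-1.19), AT3G59340 (-1.56) and AT5G35940 (-1.45). Against high R:FR at 1 h, low R:FR at 0.5 h called 410 genes, 184 of them also called in the same direction against the 0.5 h control.

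In 7 WT cotyledon libraries, all replicate 2 (high R:FR at 2 and 4 h, low R:FR at 0.5, 1, 2, 3 and 4 h), 25S ribosomal RNA was listed at 10210 to 24320 FPKM, against 0 in the other 65 libraries. Genes with stretches of sequence shared with other genes were raised in the same libraries. With these 7 left out, chosen after seeing the data, the cotyledon counts were 3182 at 0.5 h, 1222 at 1 h, 663 at 2 h, 935 at 3 h and 1230 at 4 h. This leaves 1 library per light at 2 and 4 h and 1 low R:FR library at 0.5, 1 and 3 h, assumed to vary like the other groups, so these lower counts also come from fewer libraries. With all libraries kept and a term for the 7, also chosen after seeing the data, the counts from 0.5 to 4 h were 4779, 1941, 2706, 2091 and 2632, and without genes of 5% or more shared sequence 4978, 2098, 2594, 2235 and 2441. Leaving out single libraries lowered every cotyledon count by over 1.5 times for 3 of the 4 libraries of its time. The values without high R:FR replicate 1 were 3339 at 0.5 h, 1364 at 1 h, 1615 at 2 h, 1320 at 3 h, 1365 at 4 h and 1968 at 7 h, and without high R:FR replicate 2 they were 3394, 1039, 1442, 1272, 1523 and 1814. Without low R:FR replicate 2 they were 3272 at 0.5 h, 1377 at 1 h, 1209 at 2 h and 1032 at 3 h, and without low R:FR replicate 1 they were 1050 at 4 h and 1522 at 7 h. The share of higher genes was 53.8% at 0.5 h, 56.7% at 1 h, 49.9% at 2 h, 49.1% at 3 h, 42.0% at 4 h and 41.9% at 7 h. On FPKM as deposited it was 36.9%, 55.05%, 67.9%, 72.8%, 67.6% and 69.3% in the same order, and after quantile normalization 37.9%, 38.9%, 57.2%, 39.5%, 47.0% and 45.9%.

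**Figure D2:**
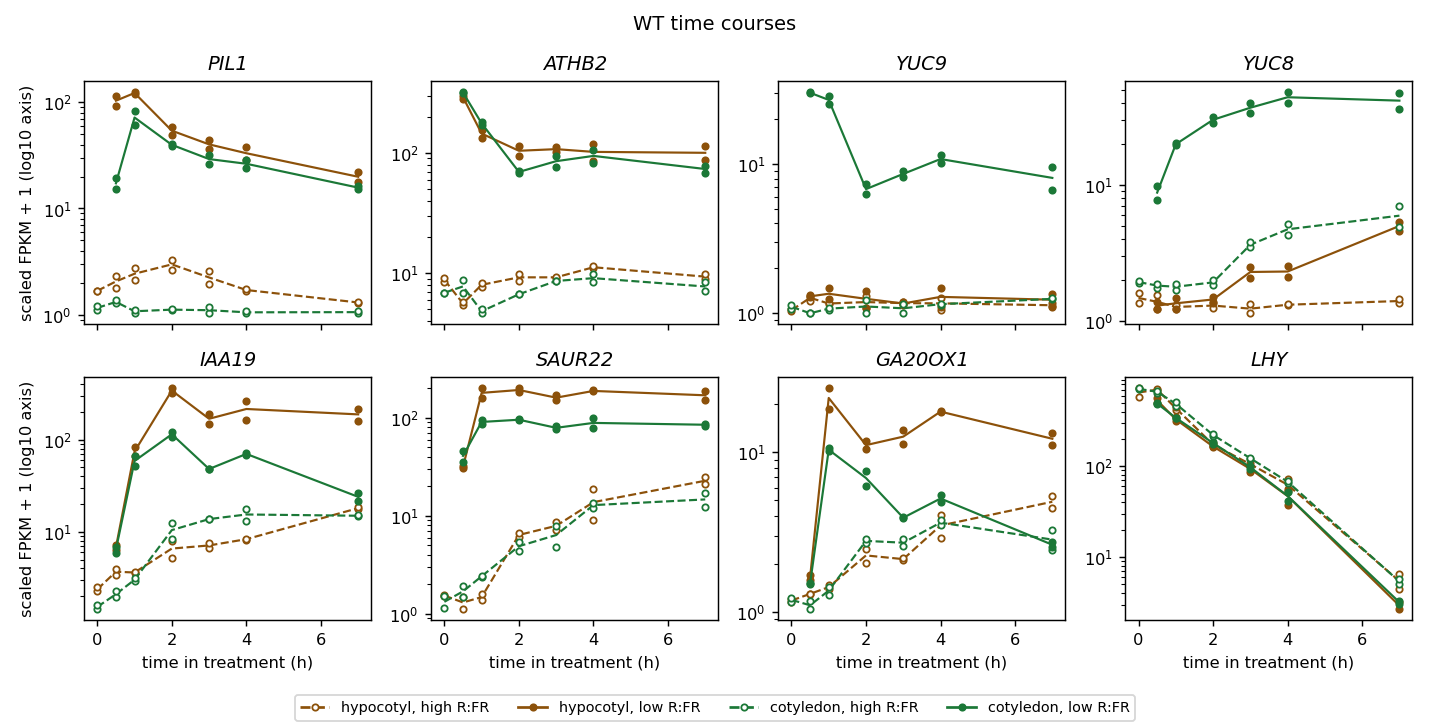
Scaled FPKM (log10 axis of FPKM + 1) of 8 genes in WT over the hours of treatment; points are single libraries, 2 per group, and lines join group means of hypocotyl and cotyledon in high and low R:FR. YUC9 at 0.5 h stands at 29.1 FPKM in the cotyledon in low R:FR and at 0.298 in the hypocotyl.

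By list, fewer SAUR and wall genes rose in the cotyledon than in the hypocotyl at 3 h, and 3 auxin synthesis genes rose against 2. Of 18 shade markers 15, 15, 16, 12, 12 and 11 rose from 0.5 to 7 h (15, 16, 17, 12, 14 and 12 adjusted over the list alone). Of 10 auxin synthesis genes 4 rose and 2 fell at 0.5 h, and 3 rose and 3 fell at 3 h (4 and 3 adjusted over the list alone); YUC2, YUC8 and YUC9 rose at each of the 6 times. The camera call of this list held with an estimated correlation at 0.5, 1 and 7 h but not at 3 h (adjusted p = 0.155) or 4 h (adjusted p = 0.0757), and no call was made at 2 h. Of 28 SAUR genes 22 rose at 0.5 h, 22 at 1 h, 16 at 3 h and 10 at 7 h. The SAUR call was lost with an estimated correlation at 3 h (adjusted p = 0.0943), 4 h (0.116) and 7 h (0.484). Of 18 auxin-induced genes 15 rose at 1 and 2 h and 9 at 7 h, with GH3.3 at 3.12 (SE 0.30) and ACS8 at 3.56 (SE 0.29) at 4 h; at 0.5 h the call was lost (adjusted p = 0.0548 with an estimated correlation). Expansins and xyloglucan endotransglucosylases were mixed, 3 up and 3 down of 17 at 3 h, although XTH15 rose by 5.40 (SE 0.25) at 7 h. Ethylene genes rose for 10 of 12 at 4 h, and auxin transport genes for 7 of 11 at 2 h, both calls holding with an estimated correlation. CKX5, a cytokinin-degrading oxidase, rose by 3.5 (SE 0.19) at 4 h. Chlorophyll and carotenoid genes fell for 13 of 14 at 7 h, HEMA1 by -0.90 (SE 0.13), a call that held (adjusted p = 0.0194 with an estimated correlation). At 0.5 h 9 of 18 genes of touch, wounding, cold and heat were lower in low than in high R:FR and 4 higher. Against high R:FR at 1 h, 13 markers, 4 auxin synthesis genes, 16 SAUR genes and 6 auxin-induced genes rose at 0.5 h and 3 of the touch list were lower. WRKY40, a stress-induced transcription factor gene, was at -2.40 (SE 0.37), but at 0.37 against high R:FR at 1 h, where it was not called (limma adjusted p = 0.809).

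The series is about tissue-specific responses, and the difference between the tissues was tested directly. YUC9 responded more in the cotyledon, and most SAUR genes responded more in the hypocotyl. Over the 6 times 8990 genes responded differently (limma F test of the interaction), 4323 with a mean log2 change that was higher in the hypocotyl and 4667 with one that was lower there, whatever the sign in each tissue. Among genes that rose more in the hypocotyl, by the mean difference of log2 changes, were SAUR15 (2.89, adjusted p = 2.42e-17), the peptide genes DVL21 (2.81), RTFL18 (2.42) and RTFL20 (2.42), IAA6 (2.54) and PHI-1 (2.48). Among those that rose more in the cotyledon were AT3G21330 (-3.64), YUC9 (-3.42, adjusted p = 4.57e-26), AT5G02540 (-2.81), AT5G22500 (-2.60) and GA2OX6, which inactivates gibberellins (-2.58). AT5G66053 had a difference of -3.16 because it fell in the hypocotyl, by a mean of -3.0, and was not called in the cotyledon. Of 28 SAUR genes 26 had a higher mean change in the hypocotyl and 1 a lower one, of 17 wall genes 14 and 2, and of 10 auxin synthesis genes 2 and 5.

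Many genes still moved together in both tissues. At 0.5 h 2975 genes were called in the same direction in both (662 by chance from the counts), at 1 h 801 (157), at 2 h 1243 (380.1), at 3 h 830 (353), at 4 h 1076 (455) and at 7 h 937 (683). Genes called in opposite directions numbered 22, 20, 157, 277, 296 and 869. Those higher in the hypocotyl and lower in the cotyledon numbered 12, 18, 82, 165, 203 and 500 (318, 81.02, 180.1, 158, 210.0 and 339.8 by chance), and the reverse 10, 2, 75, 112, 93 and 369 (339.5, 66.2, 199.8, 193, 219 and 316 by chance). Both were above chance at 7 h alone, where all 869 had a called interaction. The flavonoid gene CHS was one of these, at -1.56 (SE 0.37) in the hypocotyl and 2.46 (SE 0.37) in the cotyledon. Across all genes the changes in the tissues correlated with Pearson's r of 0.461 at 0.5 h and 0.112 at 7 h, genes not being independent replicates. With high R:FR at 1 h as the control, which called 521 and 410 genes at 0.5 h, 139 genes were shared. A 0.5 h control standing earlier in the light period in both tissues would itself move genes alike. The chance value at 0.5 h leaves this out, so the 2975 shared genes cannot be read as a shared response to low R:FR alone. Without the 7 libraries with ribosomal RNA values 484, 396, 404 and 476 were shared at 1, 2, 3 and 4 h. The chance values above belong to the main counts and do not apply to these smaller sets of calls. Without single libraries the shared counts fell to 1853 at 0.5 h (hypocotyl high R:FR replicate 1), to 516 (hypocotyl high R:FR replicate 2) and 486 (cotyledon high R:FR replicate 2) at 1 h, and, in the order of cotyledon high R:FR replicate 1, replicate 2 and the low R:FR library named above for that time, to 826, 773 and 669 at 2 h, 529, 520.0 and 452 at 3 h, 655, 674 and 558 at 4 h, and 582, 528 and 446 at 7 h.

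The mutated genes were looked at first in the mutants. PIF7 (AT5G61270, chromosome 5, 24638773 to 24640600) was lower in pif7-1. In high R:FR it stood at 11.3 ± 2.96 FPKM (n = 2) against 29.4 ± 0.611 in WT hypocotyls (n = 2), a log2 difference of -1.32 (SE 0.17) with a limma adjusted p of 1.06e-08, and at 10.1 ± 2.80 against 72.7 ± 2.89 in cotyledons (-2.75 (SE 0.17)). In low R:FR the differences were -2.56 (SE 0.17) and -3.51 (SE 0.17). In WT cotyledons low R:FR lowered PIF7, by -0.87 (SE 0.17) at 7 h. TAA1 (AT1G70560, chromosome 1, 26604855 to 26607503) was not lower in sav3-2 in high R:FR than in WT at 3 h, at 3.79 ± 0.785 FPKM (n = 3) against 3.85 ± 1.53 in hypocotyls and 13.6 ± 1.77 against 10.7 ± 2.08 in cotyledons. WT libraries in high R:FR stood at 4.59 and 6.15 FPKM in hypocotyls at 4 h, and 11.55 and 10.4 in cotyledons. At 7 h they stood at 6.13 and 5.75, and 19.78 and 17.39, above all sav3-2 libraries. The comparison thus depends on the WT time used, and the level of TAA1 does not check that label. In low R:FR the hypocotyl difference of -0.63 (SE 0.23) was called (adjusted p = 0.0283), and the call was lost in a fit within the tissue (-0.69) and without WT low R:FR replicate 1 (-0.46) or sav3-2 low R:FR replicates 2 (-0.62) or 3 (-0.52).

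The mutants bear on the roles of PIF7 and TAA1 in the response at 3 h. Their clock genes, however, stood at levels that WT reached later than 3 h, which bears on every value below whatever its cause. With a single allele per gene, PIF7 still detected in pif7-1 and this offset, they cannot settle whether either gene is needed. Matched to the WT time course in high R:FR on the 22 clock genes, WT libraries of 3 h fell at 2.7 to 3.4 h. The high R:FR libraries among them were matched with 3 h left out of the course. The mutant high R:FR libraries fell at 5.9 to 7 h (group means 7 h for the pif7-1 hypocotyl, where the time course ends, 6.6 h for its cotyledon, 6.2 h and 6 h for sav3-2), and the low R:FR libraries at 4.9, 4.5, 4.2 and 4.2 h. LHY in high R:FR stood at 4.88 ± 0.162 FPKM in the pif7-1 hypocotyl and 10.1 ± 3.93 in sav3-2, against 104 ± 5.37 in WT at 3 h. The mutant effects are therefore given in 2 ways: against WT at 3 h as planned, and "time-matched", an added comparison chosen after seeing the data in which WT is interpolated between its time points to the matched time of each mutant group. For response differences, WT low R:FR was taken at 4 to 4.7 h of its own course and WT high R:FR at 6 to 7 h. WT thus had longer in low R:FR than the mutants, and its 2 lights came from unlike times. For low R:FR within a mutant, the WT high R:FR change between the 2 matched times was subtracted. This adds groups, which by itself can lower the number of calls.

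**Figure D3:**
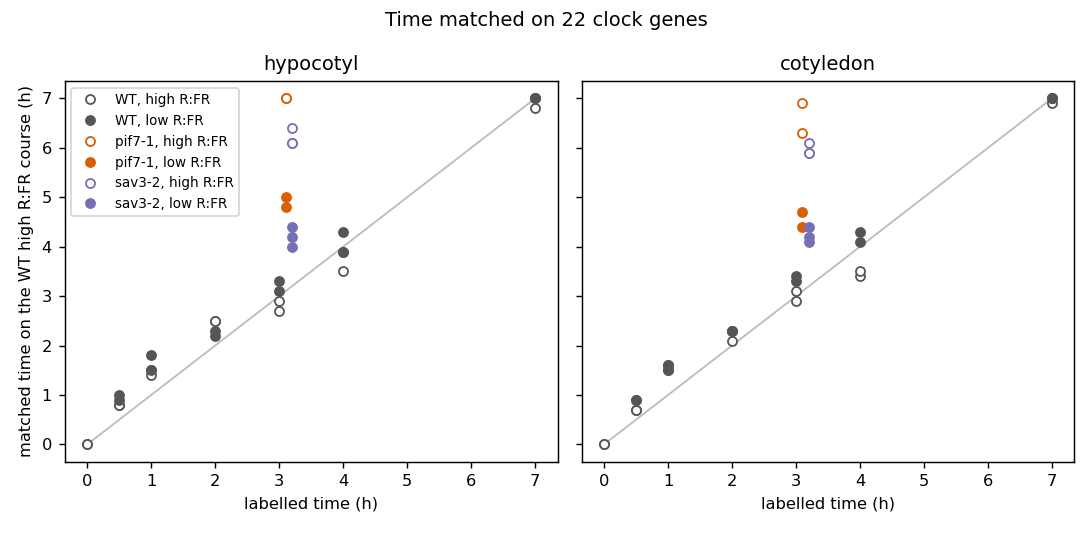
Time at which each library best matched the WT time course in high R:FR on the 22 clock genes, in h, against the labelled time in h, for hypocotyl and cotyledon; each point is a library and the line marks equal times. The mutant libraries, all labelled 3 h, lie at 4 h or later, the high R:FR ones at about 6 to 7 h.

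In pif7-1 cotyledons YUC9 and YUC2 were not called in low R:FR (adjusted p = 0.0555 and 0.0722), while PIL1, ATHB2 and HFR1 rose. YUC9 reached 0.355 ± 0.0502 FPKM in low R:FR against 7.59 ± 0.582 in WT, and its response differed by -2.56 (SE 0.23) from WT (adjusted p = 2.29e-10; time-matched -2.65 (SE 0.22), adjusted p = 2.49e-11). YUC2 reached 3.54 ± 6.55e-05 against 15.6 ± 0.919 FPKM, a difference of -1.32 (SE 0.22) (time-matched -1.42, adjusted p = 4.86e-05). The YUC8 difference of -1.32 (SE 0.29) was called against WT at 3 h but not when time-matched (-0.92, adjusted p = 0.203). PIL1 rose by 4.89 (SE 0.15) in pif7-1 cotyledons and 4.87 (SE 0.15) in its hypocotyls, ATHB2 by 4.54 and 4.28, and HFR1 by 5.95 and 3.94. HFR1 responded more than in WT in the cotyledon, by 2.22 (SE 0.30) (time-matched 1.49, adjusted p = 0.00304). Of 10 auxin synthesis genes 3 responded less than in WT in the cotyledon (time-matched 2) and the others were not called. The limma camera test of this list had an adjusted p of 0.0501 against WT at 3 h and 3.19e-05 time-matched (0.00352 with an estimated correlation). Of 18 shade markers 17 rose in the pif7-1 hypocotyl and 15 in its cotyledon (time-matched 17 and 13). Compared with WT, 4 markers responded less and 4 more in the hypocotyl, and 2 less and 3 more in the cotyledon (time-matched 3 and 1, 2 and 1).

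Further genes with a weaker response in pif7-1 under both comparisons were, in the cotyledon, GH3.3 (-2.10, time-matched -2.29), CKX5 (-1.55, -1.68), ST2A (-2.23, -2.58), GA2OX6 (-2.65, -2.23) and ACS4 (-1.44, -1.70), and, in the hypocotyl, IAA5 (-1.83, -1.53), ACS4 (-1.44, -1.67), GA20OX1 (-1.86, -1.06), SAUR68 (-2.26, -1.31) and ST2A (-2.60, -3.71). Of 28 SAUR genes 26 still rose in the pif7-1 hypocotyl. Their response differed from WT for 14, all lower, against WT at 3 h and for 2 when time-matched. Of 18 auxin-induced genes 14 rose in the hypocotyl and 10 in the cotyledon, and 8 and 5 responded less than in WT (time-matched 4 and 2); with an estimated correlation neither camera call was kept (adjusted p = 0.159 and 0.520, time-matched 0.379 and 0.0604). Of 12 ethylene genes 6 responded less in the hypocotyl (time-matched 4), a call that held.

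Low R:FR called 5830 genes in the pif7-1 hypocotyl (2646 higher, 3184 lower) and 4205 in its cotyledon (1653, 2552), and the response differed from WT for 3500 and 1675 genes. Time-matched, 3336 and 1330 were called for low R:FR, and 1646 and 73 for the difference from WT. In high R:FR 10337 genes of the hypocotyl and 7828 of the cotyledon differed from WT at 3 h, and 7548 and 2734 when time-matched. Several genes named by the rule for the largest differences were not called when time-matched. In the hypocotyl the response difference of AT5G62360 was -3.69 and, when time-matched, -0.26, and that of GRP7 was -2.86 and -0.02. In the cotyledon that of PORB was -2.88 and -0.36, and that of COR15B -3.29 and -0.09. LHY in the cotyledon had 2.60 and 0.02. LHY is among the clock genes used to choose the matched time, so its small time-matched value was at least partly built in. ICL, M17 and HSFA6A in the hypocotyl had differences of 3.80, 3.73 and 3.64, of which ICL and HSFA6A stayed called when time-matched (3.79, 1.94). CYP79F1 and BCAT4, genes of glucosinolate synthesis, were lower in the pif7-1 cotyledon in high R:FR (-4.41 and -4.40; time-matched -4.41 and -4.16). Of 13 apex markers 9 were lower in the pif7-1 hypocotyl in high R:FR, of 15 cell division genes 14 were lower, and all 3 root markers were higher (time-matched 5, 15 and 2). In limma camera tests the adjusted p were 0.02 for apex, 0.000306 for cell division and 0.339 for root, and 0.959 for each with an estimated correlation. Without pif7-1 low R:FR replicate 2 the response counts were 3801 in the hypocotyl and 2219 in the cotyledon and the differences 1838 and 843. Without pif7-1 high R:FR replicate 2 the cotyledon gave 2429 and 940.0, and the hypocotyl difference was 2278 without pif7-1 high R:FR replicate 1 and 2264 without WT high R:FR replicate 1. The share of higher genes among the cotyledon differences was 38.5%, 29.3% on FPKM as deposited and 52.7% after quantile normalization.

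**Figure D4:**
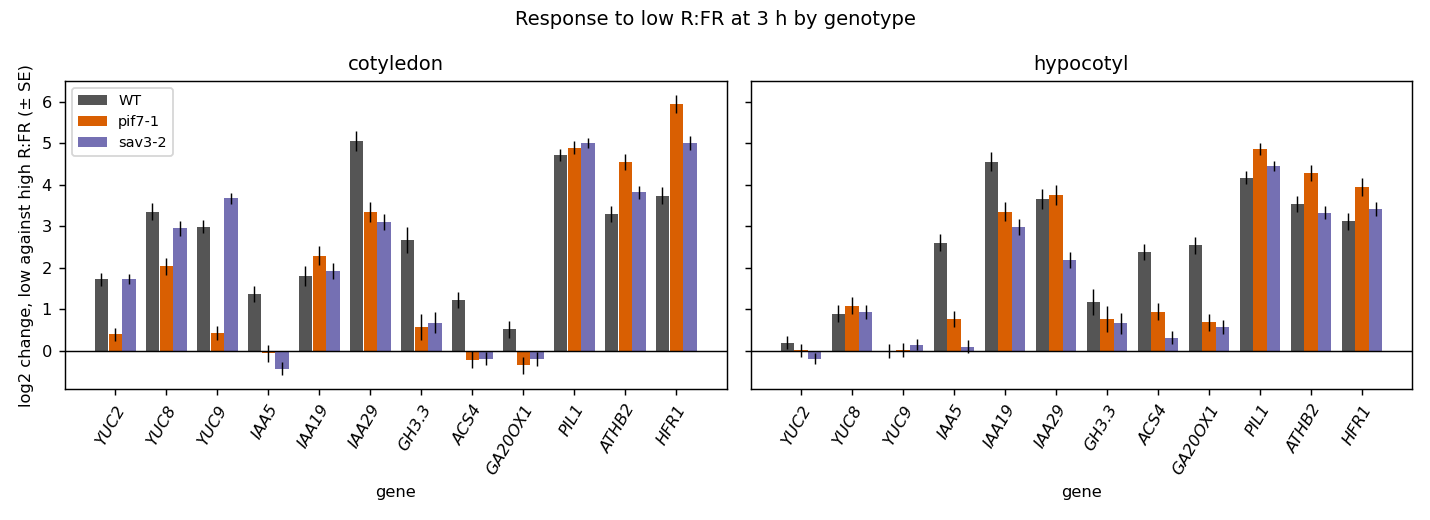
Log2 change between low and high R:FR at 3 h (error bars, limma SE) of 12 genes in WT, pif7-1 and sav3-2 in cotyledon (left) and hypocotyl (right), each against high R:FR of its own genotype, with no time matching. In the cotyledon YUC9 stands at 3.00 in WT, 0.44 in pif7-1 (adjusted p = 0.0555) and 3.67 in sav3-2, and PIL1 at 4.72, 4.89 and 5.01.

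In sav3-2, YUC2, YUC8 and YUC9 still rose in the cotyledon and most shade markers in both tissues, while several auxin-induced genes rose less than in WT. In the cotyledon YUC9 reached 14.7 ± 3.79 FPKM in low R:FR (n = 3), YUC8 41.1 ± 4.26 and YUC2 16.1 ± 0.953, and PIL1 rose by 5.01 (SE 0.13) there and 4.46 (SE 0.13) in the hypocotyl. IAA5 was not called in the sav3-2 hypocotyl (0.10 (SE 0.16), adjusted p = 0.710) and rose by 2.61 (SE 0.20) in WT, a difference of -2.51 (SE 0.25) (limma adjusted p = 2.51e-09; time-matched -2.43, adjusted p = 4.83e-09). IAA19 rose by 2.98 against 4.56, differing by -1.58 (SE 0.30) (time-matched -0.85), and IAA29 differed by -1.48 (-1.21), IAA6 by -2.40 (-1.47), GH3.1 by -1.65 (-1.50), ACS4 by -2.06 (-2.23) and GA20OX1 by -1.98 (-1.43). In the cotyledon GH3.3 differed by -2.0 (SE 0.39) (time-matched -2.34) and ACS4 by -1.42 (SE 0.25) (-1.84).

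Of 18 auxin-induced genes 12 rose in the sav3-2 hypocotyl and 9 responded less than in WT (12 adjusted over the list alone; time-matched 9), a camera call that held with an estimated correlation (adjusted p = 0.0386; time-matched 0.0251). In the cotyledon 10 rose and 6 responded less (time-matched 4), the camera adjusted p of limma with an estimated correlation being 0.425 against WT at 3 h and 0.00999 time-matched. Of 28 SAUR genes 26 rose in the hypocotyl and 7 responded less (time-matched 2; adjusted p = 0.375 with an estimated correlation, time-matched 0.879). Of 18 shade markers 17 rose in the hypocotyl and 15 in the cotyledon (time-matched 16 and 12). Compared with WT, 4 responded less in the hypocotyl, and 2 less and 1 more in the cotyledon (time-matched 4 and 1 less). The limma camera test gave a lower marker response in the hypocotyl (adjusted p = 0.0276, 0.460 with an estimated correlation; time-matched 0.00123 and 0.191), and in the cotyledon when time-matched (0.0324 and 0.482). Within the sav3-2 hypocotyl, 13 of 15 cell division genes were lower in low than in high R:FR (KN -0.86, and time-matched 1 lower). The limma camera adjusted p was 0.588 with an estimated correlation.

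Low R:FR called 7042 genes in the sav3-2 hypocotyl (3051 higher, 3991 lower) and 5589 in its cotyledon (2406, 3183), and 3838 and 2062 responded differently from WT. Time-matched, 4726 and 1843 were called for low R:FR and 2369 and 49 for the difference, and without the 7 libraries with ribosomal RNA values the cotyledon difference was 1279. In high R:FR 6865 and 7066 genes differed from WT at 3 h, and 4909 and 1141 when time-matched. Among the largest differences in response, COR15A in the cotyledon (-3.77) was not called when time-matched (-1.74), nor was GRP7 in the hypocotyl (-3.10; -0.55), whereas OEP6 in the hypocotyl was (-3.23; -1.24). The sav3-2 hypocotyl in high R:FR had higher EARLI1 (5.18; time-matched 3.49) and lower LEA18 (-4.21; -3.16). Many of the other genes that the rule named in the mutants were transfer RNA, microRNA and small nucleolar RNA genes, which are not described singly here. The hypocotyl difference fell to 2026 without WT high R:FR replicate 1 and 2529 without WT low R:FR replicate 1, and the cotyledon difference to 1318 without WT high R:FR replicate 2 and 1341 without WT low R:FR replicate 1. The share of higher genes was 43.3% for low R:FR in the hypocotyl (54.0% on FPKM as deposited, 47.2% after quantile normalization) and 54.6% for high R:FR there (49.6% and 44.5%). For the differences it was 48.9% in the hypocotyl (62.9% on FPKM as deposited, 50.2% after quantile normalization) and 40.7% in the cotyledon (31.4% and 55.0%).

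To compare the mutants with WT on genes not chosen on the 3 h libraries, genes called in WT at both 2 and 4 h in 1 direction were followed at 3 h. They were chosen for their response in WT and no set chosen in a mutant was followed, so lower medians do not show a generally weaker response. At 3 h low R:FR called 2307 cotyledon genes in WT, 4205 in pif7-1 and 5589 in sav3-2. In the hypocotyl it called 6432, 5830 and 7042. These counts do not rank the genotypes, since sav3-2 had more libraries per group and the 2 lights of each mutant matched unlike times. Time-matched, pif7-1 and sav3-2 gave 1330 and 1843 in the cotyledon, and 3336 and 4726 in the hypocotyl. In the hypocotyl, the 1766 genes that rose had a median log2 change of 0.65 ± 0.06 (SD between libraries) in WT, 0.44 ± 0.05 in pif7-1 and 0.41 ± 0.10 in sav3-2, with fry p of 0.000358 and 2.08e-05 in limma for a lower response. The 1895 genes that fell had -0.52 ± 0.11, -0.18 ± 0.04 and -0.14 ± 0.05, with fry p of 9.83e-10 and 4.16e-11 in limma. In the cotyledon, 544 genes that rose had 0.68 ± 0.01, 0.40 ± 0.05 and 0.44 ± 0.05, with fry p of 4.71e-05 and 0.000136 in limma. The 612 genes that fell there had -0.37 ± 0.04, -0.31 ± 0.07 and -0.28 ± 0.04, with fry p of 0.0285 and 0.00432 in limma. Time-matched, with genes chosen at 2 and 3 h, the 1892 rising hypocotyl genes had medians of 0.52 in pif7-1 against 0.61 in WT, and 0.48 against 0.58 for sav3-2. The 1691 falling ones had -0.29 against -0.54 and -0.29 against -0.55. In the cotyledon, 525 rising genes had 0.51 against 0.65 and 0.51 against 0.66, and 527 falling ones -0.35 against -0.45 and -0.33 against -0.46. Without the 7 libraries with ribosomal RNA values the cotyledon medians were 1.08 in WT, 0.68 in pif7-1 and 0.76 in sav3-2 for rising genes, and -0.66, -0.40 and -0.43 for falling ones. With hypocotyl genes called at 4 h alone, the rising ones had 0.44, 0.22 and 0.22 (WT, pif7-1, sav3-2). In both mutants 4051 genes were called in the same direction in the hypocotyl (986 by chance) and 15 in opposite directions, and 3302 and 2 in the cotyledon (574 by chance). The high R:FR libraries of both mutants matched later times than their low R:FR libraries, an offset that the chance values leave out. Time-matched, 2345 and 881 were called alike (372 and 59.3 by chance) and 1 and 0 in opposite directions, but these comparisons share WT libraries.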

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

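Apart from the splits of libraries and the interaction counts, the tests here were chosen after seeing the data. What would speak for or against an explanation was written down before the deciding values were seen for the tests at 0.5 h, the overall time match and the splits, and after for shared sequence, ribosomal RNA, fixed clock shifts, organ shares and the cotyledon time match.

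The response to low R:FR differed between hypocotyl and cotyledon for 8990 genes by the test of the interaction. It differed from WT for 3500 genes in pif7-1 hypocotyls and 1675 in pif7-1 cotyledons, and for 3838 genes in sav3-2 hypocotyls and 2062 in sav3-2 cotyledons. The counts of 2 libraries per group moved with single libraries, as given with the results.

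In 7 cotyledon libraries, all replicate 2, 25S ribosomal RNA reached 24320 FPKM. It was at exactly 0 in the other 65 libraries, which argues against more ribosomal RNA in these samples as the cause, since traces are left by any preparation. Against the other replicate of their group, 90 genes with 50% or more shared sequence stood higher by a median of 5.27 on the log2 scale. Those with 5% to 50% (421 genes) stood higher by 0.228, and 11570 genes with none were shifted by about 0. Only genes whose mean log2(FPKM + 1) over these groups reached that of an FPKM of 5 were used, the 7 libraries included. A gene near 0 in the other replicates entered only with a large shift, so the size of 5.27 is partly set by this filter. The gap between the first and last class was 5.27, with the same limit. Of the 90 genes, 89 were raised by over 0.5. Of the 11570 genes with none, 14 were raised and 22 lowered by over 0.5. This direction would follow if reads that match several places were kept or shared out differently when these 7 files were made, which stays a hypothesis. The labels do not give the settings per library, and no biological explanation was tested.

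At 0.5 h, 5452 genes in the hypocotyl and 5102 in the cotyledon were called, more than at 1 h. Against high R:FR at 1 h the same low R:FR libraries called 9.56% as many genes in the hypocotyl and 8.04% in the cotyledon, which is consistent with the 0.5 h control standing earlier in the light period than the low R:FR samples. On the clock genes, low R:FR at 0.5 h matched 0.9 to 1 h in the hypocotyl and 0.9 h in the cotyledon. The 0.5 h control matched 0.8 h and 0.7 h, and the 1 h control 1.4 to 1.5 h and 1.5 to 1.6 h. These controls were matched with their own time left out of the WT course, the low R:FR libraries with every time kept. The values can therefore not be set beside each other. Outside the clock list, the 0.5 h differences correlated with the change from 0 to 1 h in high R:FR (Pearson's r of 0.460 and 0.449). At 2 to 7 h r lay between -0.206 and 0.00652, genes not being independent replicates. How far such an offset accounts for the calls stays open. Of the 0.5 h calls, 19.97% in the hypocotyl and 15.8% in the cotyledon were called in the same direction at 1 h, values that lie between those set for and against an early lasting response, so that this explanation stays open.

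The mutant libraries of 3 h matched later WT times on the clock genes. A fixed shift of the clock is argued against by gaps of 2.1, 2.1, 2 and 1.8 h between high and low R:FR libraries of a mutant and tissue, the high R:FR ones being later, against 0.4 h at most in WT at 3 h. In the WT cotyledon at 4 h, high R:FR libraries matched 3.4 and 3.5 h and low R:FR libraries 4.1 and 4.3 h. At 3 and 4 h the WT high R:FR libraries were matched with their own time left out, the low R:FR libraries with every time kept. These WT gaps may therefore come in part from unlike matching, and their order is not read as a result. After time matching, at most 34.9% as many cotyledon genes differed from WT in high R:FR. In the hypocotyl 73.0% as many did in pif7-1 and 71.5% in sav3-2. Collection at a later time of day may account for the cotyledon, and it cannot be told whether it covers the hypocotyl. A clock moved by the mutation would lower these counts as well, so their fall does not favour later collection. The gaps between the lights also argue against 1 later collection time shared by the high and low R:FR libraries of a mutant. Other shares of shoot apex or root are not excluded, since of the apex, root and division lists 1 was called in the cotyledon (cell division, higher in sav3-2; limma camera adjusted p = 0.02, and 0.959 with an estimated correlation), although the smaller cotyledon shift was 3 h. An effect of the mutations on the pace of the clock was not tested.

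In sav3-2, 7042 genes were called for low R:FR in the hypocotyl (highest other split 993) and 5589 in the cotyledon (highest other split 39). The 10 splits of 6 libraries are too few for a share under 0.05, and 1 of the 10 gave as many in each tissue, the real one.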

How the results depend on the processing

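Of the alternatives, the pseudocount, the filters, FPKM as deposited, quantile normalization, the replicate block, the fit within the tissue, the estimated correlation, the choice at 4 h alone, genes with failed estimates kept and leaving out libraries were planned, and the others were chosen after seeing the data. For single genes, 221 of 232 values kept direction and call with a pseudocount of 0.1, 231 with no filter, 176 of 176 with the stricter filter, 230 as deposited, 231 with quantile normalization, 229 with the block, 202 of 207 within the tissue and 61 of 112 when time-matched. Leaving out 1 library kept 2683 of 2734. Genes with failed estimates kept changed none of 57 results. Replicate numbers did not pair most libraries (WT groups correlated above 0.1 in 13 of 78 hypocotyl and 26 of 78 cotyledon pairs; the pif7-1 hypocotyl groups had r = 0.249), so the block is given here alone. For the results below that moved, the cause was not tested, except that fewer samples or another control are part of the construction.

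Medians of WT-selected genes are given as WT, pif7-1, sav3-2. For rising cotyledon genes they were 0.77, 0.50 and 0.50 with a pseudocount of 0.1, 0.46, 0.30 and 0.31 on FPKM as deposited, 0.65, 0.46 and 0.50 with quantile normalization, 0.44, 0.27 and 0.29 with genes called at 4 h alone, and 1.08, 0.68 and 0.76 without the 7 libraries with ribosomal RNA values. In WT alone they moved to 0.70 with no filter, 0.58 with the stricter filter, 0.59 with the replicate block, 0.67 with a term for the 7 libraries and 0.66 without genes of 5% or more shared sequence. Falling cotyledon genes moved to -0.43 (WT) and -0.35 (sav3-2) as deposited, -0.47 (WT) with quantile normalization, -0.30 (WT) and -0.22 (sav3-2) at 4 h alone, and -0.66, -0.40 and -0.43 without the 7 libraries. Hypocotyl genes called at 4 h alone had 0.44, 0.22 and 0.22 for rising and -0.40 (WT) and -0.13 (pif7-1) for falling genes. TAA1 in sav3-2 hypocotyls in low R:FR was -0.40 with the block and -0.69 within the tissue, and the 1 h hypocotyl count was 1982 within the tissue. List calls numbered 76 with an estimated correlation.

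Without the 7 libraries, the cotyledon counts were 3182, 1222, 663, 935 and 1230 from 0.5 to 4 h, the overlaps 484, 396, 404 and 476 from 1 to 4 h, and the sav3-2 cotyledon response difference 1279. With high R:FR at 1 h as the control, 521 and 410 genes were called at 0.5 h and 139 overlapped, and WRKY40 in the cotyledon stood at 0.37. Time-matched, the pif7-1 counts were 3336 and 1330 for low R:FR, 1646 and 73 for the response difference and 2734 for high R:FR in the cotyledon. The sav3-2 counts were 1843 for low R:FR in the cotyledon, 2369 and 49 for the difference and 1141 for high R:FR in the cotyledon. In high R:FR, CHS in pif7-1 hypocotyls turned to 1.31. Response differences turned for AGP7 (0.24) and AT5G14920 (0.13) in pif7-1 hypocotyls and for AT5G62360 in the cotyledons of pif7-1 (0.87) and sav3-2 (0.20).

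Leaving out 1 library at a time gave these lowest and highest values. Hypocotyl counts were 2670 to 4738 at 0.5 h, 1387 to 2405 at 1 h, 4035 to 5366 at 2 h, 4728 to 6698 at 4 h. Cotyledon counts were 3272 to 3914 at 0.5 h, 1039 to 1530 at 1 h, 1209 to 1841 at 2 h, 1032 to 1705 at 3 h, 1050 to 1986 at 4 h, 1522 to 2134 at 7 h. Overlaps were 1853 to 2595 at 0.5 h, 486 to 683 at 1 h, 669 to 1081 at 2 h, 452 to 741 at 3 h, 558 to 985 at 4 h, 446 to 832 at 7 h. In pif7-1, low R:FR called 3801 to 5762 genes in the hypocotyl and 2219 to 3409 in the cotyledon, and the response difference 1838 to 4639 and 843 to 1555. The sav3-2 response difference was 2026 to 4132 and 1318 to 2004. Medians of rising genes were 0.63 to 0.75 (WT) and 0.41 to 0.53 (pif7-1) in the hypocotyl, and 0.66 to 0.93, 0.40 to 0.59 and 0.41 to 0.67 (WT, pif7-1, sav3-2) in the cotyledon, and of falling cotyledon genes -0.49 to -0.36 (WT) and -0.40 to -0.27 (sav3-2). TAA1 in sav3-2 hypocotyls in low R:FR was -0.81 to -0.46.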

Other observations

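Some gene groups moved in ways the comparisons above leave aside. Named genes that code for small DEVIL/ROTUNDIFOLIA peptides, a family not tested as a set, include RTFL18, RTFL13, RTFL20 and DVL21: RTFL18 rose by 7.26 (SE 0.65) in the hypocotyl at 3 h and RTFL13 by 5.38 (SE 0.96) in the cotyledon. These SE were larger than those given above for PIL1 and IAA19. All of these peptide genes have short annotated intervals, where the FPKM may be less certain, which was not tested. Of 18 flavonoid genes, 10 fell and 0 rose at 7 h in the hypocotyl. In the cotyledon 2 fell and 5 rose (2 and 5 adjusted over the list alone), and the others were not called. The hypocotyl camera call was lost with an estimated correlation, as given above, and the list was not tested as a set for a tissue difference. In high R:FR at 3 h all 18 were lower in pif7-1 hypocotyls than in WT, with LDOX at -3.05 (SE 0.43) and CHS at -0.88 (SE 0.37), but 3 when time-matched, where CHS was higher than in WT at 1.31 (SE 0.37) (limma adjusted p = 0.00552). That camera test gave an adjusted p of 4.54e-07, and 0.959 with an estimated correlation. Light-harvesting and Calvin cycle genes were mostly not called in low R:FR: 10 of 25 fell in the hypocotyl at 7 h (adjusted p = 0.676 with an estimated correlation) and 3 in the cotyledon.

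Photoreceptor, PIF and light signalling genes were called in camera from 2 to 7 h in the cotyledon, where 8 of 27 rose and 1 fell at 7 h, but not with an estimated correlation (adjusted p = 0.398 at 7 h). Brassinosteroid genes rose for 9 of 16 in the cotyledon at 4 h (adjusted p = 0.0550 with an estimated correlation). Gibberellin genes rose for 5 of 14 in the cotyledon at 1 h (8 adjusted over the list alone), a call that held (adjusted p = 0.000900 with an estimated correlation). Cytokinin genes fell for 7 of 13 and rose for 2 in the cotyledon at 7 h (adjusted p = 0.0535 with an estimated correlation). Of 10 abscisic acid genes 3 rose and 1 fell in the hypocotyl at 7 h, and 2 rose in the cotyledon. Of 14 defence genes 1 rose and 4 fell in the hypocotyl, and 3 fell in the cotyledon. Of 22 clock genes 2 rose and 8 fell in the hypocotyl at 7 h, and 4 and 4 in the cotyledon. Of 11 xylem and phloem markers 2 fell in the hypocotyl at 7 h and none were called in the cotyledon (11 not called). Of 10 guard cell markers 1 rose and 3 fell in the hypocotyl at 7 h, and 1 rose in the cotyledon.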
